A study of Mus musculus with 16 samples.

How the data were processed

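RNA from subchondral bone of the mouse medial tibia was measured on 16 Agilent 1-colour arrays, 1 joint of 1 mouse per array. Male C57BL6 mice aged 10 to 12 weeks had surgery on both knees, either destabilization of the medial meniscus (DMM) or a sham operation that exposed the ligament without cutting it. Joints were taken 1 or 6 weeks later, which gave 4 groups of 4 arrays. Per the labels, bone was cut by laser microdissection from 10 µm cryosections, pooled per joint, and 100 ng of RNA was labelled with Cy3. The arrays sat on 2 slides of 8, each with 2 arrays of each group. The replicate numbers used here follow the order of the records and carry no pairing. No paired analysis was possible because the labels do not link a sham joint with a DMM joint.

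Agilent Feature Extraction 10.7.3.1 produced the scanner files, per the file headers. These deposited files hold a background-corrected intensity for each spot (gProcessedSignal), a call of whether the spot lies well above background, and probe coordinates on the mouse assembly mm9. Feature Extraction had replaced 14.3% of spot values by surrogates for signals near background. The authors also deposited a value table for 50815 probes that ranges from -1.67 to 20.43 and was read as log2, with array medians between 7.24 and 7.34. Per the submitters' processing notes it was made with limma 3.20.9. Its background, centring and normalization steps are not given in the sources used here. The 5790 probes missing from it include 0% that pass the filter described next.

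The scanner files were the source of every value unless another is named. After control spots were removed, 59305 spots of 56605 probes were left. Spots that the scanner software marked as non-uniform or as population outliers were set aside, and the other spots of a probe were averaged. The 342 probes with no spot left on at least 1 array were dropped. A probe entered when it was well above background on at least 4 of the 16 arrays, whatever the group, and 43268 probes did. Values were log2 intensities minus the 75th percentile of their array. Probe names came from the accession in the file (32994 probes), a current symbol (10224), an older symbol (520) or the name in the file (12867). For the 9270 genes with several probes the probe with the highest mean stood for the gene. This left 28250 genes or unnamed transcripts, 19754 of them with a current symbol. The position of a probe within its gene was not analysed here, since no annotation of mm9 was at hand.

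Signal at the 75th percentile ranged from 329 to 873 between arrays, and 65.1% to 79.5% of probes were well above background. Repeated spots of 1 probe differed by a coefficient of variation of 2.23% to 4.42%, and 0 spots were saturated. The median standard error of a log2 difference was 0.30 for 4 arrays against 4, 0.42 for the difference of 2 such differences, and 0.21 for 8 against 8.

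A linear model with 1 mean per group was fitted to all 16 arrays in limma 3.58.1 (lmFit, contrasts.fit and eBayes at default settings), with 12 residual and 3.01 prior degrees of freedom. P-values were 2-sided and adjusted by Benjamini-Hochberg over all 28250 genes, with a threshold of 0.05. Planned comparisons were DMM against sham at 1 week, at 6 weeks, their difference, their average, and 6 weeks against 1 week after each surgery. A 7th comparison, 6 weeks against 1 week averaged over both surgeries, was added after seeing the data. The other comparisons, gene lists, naming rule and alternatives were fixed before the data were examined. R 4.3.3, data.table (version 1.17.8), jsonlite 2.0.0, Python 3.11.15 and matplotlib 3.10.9 were used.

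The 27 gene lists covered osteoclast, osteoblast and bone matrix, osteocyte, chondrocyte and cartilage matrix, Wnt pathway, TGF-beta and BMP pathway, extracellular proteases and inhibitors, fibrous matrix and fibroblast, and tendon, ligament and synovial lining. They also covered inflammatory mediators, interferon response, macrophage and monocyte, neutrophil granule, erythroid, B cell, T and NK cell, megakaryocyte and platelet, endothelium, marrow stromal reticular cell, and adipocyte. The rest were skeletal muscle, nerve and Schwann cell, cell cycle, immediate early and heat shock, hypoxia and glycolysis, mitochondrial respiratory chain, and cytosolic ribosomal proteins. Each list was tested with limma's camera at its preset correlation of 0.01 between genes, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were alternatives. The median correlation that camera estimated was 0.342, far above the preset, so the preset test is liberal in these data. Members' adjusted p-values were also computed over each list alone.

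Named genes followed a fixed rule. Of the genes past the threshold whose 4 values in 1 group lay all above or all below the 4 of the other, up to 8 with the largest change per direction were named. This separation was not asked of the difference of effects or of averaged effects. Where fewer than 3 such genes existed, the 5 with the smallest unadjusted p per direction were named as not past the threshold. In at most 6 called lists with the smallest p, up to 4 members with the smallest p were named. A set of 24 joint and bone genes was given for the DMM comparisons whatever the result. Symbols that are accessions, clone or RIKEN names, Gm or LOC numbers were left out, also where genes were named by unadjusted p. A few of the genes this rule picked are not reported here. Mmp3, Wnt16 and Aspn, 3 of the 24, did not enter because they were well above background on 2, 0 and 2 of the 16 arrays.

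Simulated effects were added to data with the spread of these arrays to test the fit. With 4 arrays against 4, genes changed 1.5, 2, 3 and 4-fold were called in 2.9%, 21.8%, 51.7% and 68.7% of cases. With 8 against 8 these shares were 13.6%, 48.6%, 79.1% and 91.8%, and the median number of false calls was 0 at both sizes (highest of 20 sets 601 and 54). With no effect at all, camera at the preset correlation called a median of 9.5 of 27 lists (highest 17) for 4 arrays against 4 and 12 (highest 21) for 8 against 8. With an estimated correlation the median was 0. Lists shifted by 0.7 on the log2 scale were called in 96.7% and 100% of cases at the preset and in 51.7% and 68.3% with an estimated correlation.

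Alternatives were quantile normalization, the array median in place of the 75th percentile, normexp background correction with an offset of 50, the authors' value table, no filter on dim probes, a filter on all 16 arrays, and the mean of a gene's probes. For the model they were slide as a block, each slide alone, the compared arrays alone, a trend with robust variance, array weights, leaving out each array, and an unadjusted p under 0.05 with a 1.5-fold change. Leaving sham_6wk replicate 2 out of the shared fit where its group was not compared was added after seeing the data. Exact permutation tests of list means between the times were also added then. Surgical side, harvest session and RNA quality per joint are not given in the sources used here.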

Results

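Gene expression was measured in laser-dissected medial tibial subchondral bone of 16 mice: 4 each at 1 and at 6 weeks after sham surgery and after DMM, which destabilizes the joint and leads to osteoarthritis. All effects are log2 differences with their standard errors, and all p-values are 2-sided. Probes for the bone genes Bglap, Acp5 and Ctsk and the erythroid marrow gene Alas2 passed the filter, so both bone and marrow transcripts were present in the dissected tissue. Of 24 joint and bone genes chosen in advance, 21 were measured. Array sham_6wk replicate 2 was dimmer than the rest (75th percentile of signal 329, next lowest 471) and lay far from the other arrays on the first principal component (176.5, others -69.6 to 71.7).

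What did destabilization do to subchondral bone within 1 week? Bglap, which encodes the osteoblast protein osteocalcin, was higher by 1.16 ± 0.46 after DMM (sham 6.01 ± 0.76 SD, DMM 7.16 ± 0.99, n = 4 each). It lay above the sham mean on 4 of 4 DMM arrays and was higher within both slides (0.80 and 1.51), without passing the threshold (limma adjusted p = 1.0). Col10a1, a collagen of hypertrophic cartilage, was higher by 2.22 ± 1.07 (3.41 and 1.04 within slides). Acan, the cartilage proteoglycan aggrecan, was higher by 1.31 ± 0.82 (2.36 and 0.26). Among stromal genes, Dmp1 of osteocytes was higher by 0.44 ± 0.38, Col1a1 of bone matrix by 0.38 ± 0.47, the aggrecanase Adamts5 by 0.36 ± 0.22 (other probe -0.09) and the RANKL decoy Tnfrsf11b by 0.33 ± 0.38. Osteoclast genes had mean differences near 0: Acp5 -0.04 ± 0.31, Ctsk -0.08 ± 0.43 and the osteoclast-inducing cytokine Tnfsf11 -0.01 ± 0.39 (other probe 0.04). The Wnt inhibitor Sost (-0.25 ± 0.61), the cytokine Il6 (-0.59 ± 0.44), Tgfb1 (-0.23 ± 0.23) and the activin subunit Inhba (-0.27 ± 0.60) were lower. Prg4, the joint lubricant, was higher by 0.81 ± 0.87, while Col2a1 (0.07 ± 0.57), Mmp13 (0.08 ± 0.46), Postn (0.02 ± 0.62), Cxcl12 (-0.01 ± 0.19) and Vegfa (0.07 ± 0.24) were also near 0. With 1 array left out, Prg4 gave -0.05 (sham_1wk replicate 1), Acan 0.62 (the same array) and Il6 -0.09 (DMM_1wk replicate 2). Leaving out DMM_1wk replicate 1 gave Tnfsf11 -0.48, Ctsk -0.39, Dmp1 0.21 and Tnfrsf11b 0.15, and leaving out DMM_1wk replicate 2 gave Ctsk 0.33, Dmp1 0.78, Tnfrsf11b 0.65 and Sost -0.05. Col1a1 ranged from 0.17 to 0.63 (without sham_1wk replicate 3 and DMM_1wk replicate 3), and Inhba was -0.03 without sham_1wk replicate 4. In all 19 of the 21 genes moved over 1.5 times with 1 array left out and 9 changed sign. Of the 21 genes, 13 were higher and 8 lower after DMM. None passed the threshold over all genes or over these 21 alone (lowest adjusted p = 0.507).

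Across all genes, limma called 0 of 28250 at 1 week, and 273 had an unadjusted p under 0.05 (98 higher, 175 lower) where 1412 were expected by chance. The genes with the smallest unadjusted p, none past the threshold (adjusted p = 1.0 for each), included Nupr1, a stress-induced regulator of transcription. Nupr1 was higher by 0.98 ± 0.27 (sham 3.05 ± 0.26 SD, DMM 4.03 ± 0.59) on 4 of 4 arrays, by 0.96 and 1.00 within the 2 slides, but by -0.03 on its other probe. The same group held Prm1 (1.88 ± 0.51), a sperm protamine, the P450 enzyme Cyp2f2 (2.12 ± 0.71, and 2.14 and 2.10 within slides), Zfp939 (0.57 ± 0.18) and Rad51ap2 (0.57 ± 0.19). Lower were Izumo2 (-1.25 ± 0.36), the enkephalin precursor Penk (-0.61 ± 0.19, other probe -0.04), Cfap100 (-0.64 ± 0.20, other probe 0.85), Dgkg (-0.57 ± 0.18) and the mast cell signalling gene Rasgrp4 (-0.64 ± 0.22). The 4 values of DMM and of sham did not overlap for 310 genes (1.10%). The share would be 2.86% if arrays could be exchanged freely between the groups. That figure leaves out the balance of the groups over the slides, so the comparison with it decides nothing.

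Megakaryocyte and platelet genes were lower after DMM in 17 of 18 members (median -0.58, camera adjusted p = 5.56e-14, or adjusted p = 0.423 with an estimated correlation). The 4 with the smallest p were Treml1 (-0.68 ± 0.31), Gp5 (-0.75 ± 0.34), Rab27b (-0.64 ± 0.30, highest probe 0.03) and Mmrn1 (-0.63 ± 0.30), genes of platelet surface and granules. Fibrous matrix genes were higher in 31 of 36 (median 0.45, adjusted p = 3.05e-10, or 0.423 with an estimated correlation). They held the Wnt modulator Sfrp2 at 1.29 ± 0.52, the collagen cross-linker Loxl2 at 0.52 ± 0.25, Tnn at 1.62 ± 0.81 and Col3a1 at 1.70 ± 0.86. Osteoblast genes were higher in 21 of 25 (median 0.31, adjusted p = 1.11e-05, or 0.538 with an estimated correlation): beside Bglap these were Bglap2 (0.72 ± 0.36), Cgref1 (0.63 ± 0.50) and the master regulator Runx2 (0.35 ± 0.29, lowest probe -0.10). Adipocyte genes were higher in 16 of 22 (median 0.20, adjusted p = 2.15e-05, or 0.423 with an estimated correlation), led by the adipsin gene Cfd (2.20 ± 0.83) and the lipid droplet genes Plin4 (1.25 ± 0.55), Cidec (1.59 ± 0.78) and Adig (1.09 ± 0.61). Neutrophil granule genes were lower in 20 of 24 (median -0.24, adjusted p = 9.32e-05, or 0.538 with an estimated correlation). These included the chemokine receptor Cxcr2 (-0.54 ± 0.26), the collagenase Mmp8 (-0.42 ± 0.33), the gelatinase Mmp9 (-0.26 ± 0.17) and Padi4 (-0.35 ± 0.31). These 5 lists kept their sign within both slides, but 3 of them rested on 1 array. Without DMM_1wk replicate 1 osteoblast (0.15, camera adjusted p = 0.0984), adipocyte (0.01, 0.0984) and neutrophil genes (0.01, 0.989) were not called. The neutrophil mean of that array was -0.63, where the other 3 DMM arrays gave -0.05 to 0.47, and the neutrophil list was not called without sham_1wk replicate 4 either (-0.17, 0.0576). Platelet and fibrous matrix genes were called with each of the 8 arrays left out, but the fibrous matrix median was 0.21 without DMM_1wk replicate 1 and the platelet median ranged from -0.91 to -0.40. B cell genes differed between slides: 19 of 21 were higher (median 0.22, adjusted p = 9.54e-04, or 0.577 with an estimated correlation), but the medians were -0.41 and 0.82 within slides. This list was not called without DMM_1wk replicate 3 (0.12, 0.141), DMM_1wk replicate 4 (0.05, 0.702) or sham_1wk replicate 4 (-0.03, 0.997). Pax5 (0.35 ± 0.25, other probe -0.10), Rag1 (0.46 ± 0.52) and Cr2 (0.23 ± 0.26) led the list.

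Further lists were called higher at 1 week: Wnt pathway (median 0.15), endothelium (0.14), osteocyte (0.27), ribosomal proteins (0.08), chondrocyte (0.07), respiratory chain (0.07) and extracellular proteases (0.10). T and NK cell genes (-0.17) and macrophage genes (-0.09) were lower. Each of these 9 lists lost its call when a single array was left out. Leaving out DMM_1wk replicate 1 ended the call of osteocyte (0.06, camera adjusted p = 1.0), endothelial (-0.02, 0.982), Wnt (0.709), protease (-0.04, 0.863), chondrocyte (0.04, 0.327), respiratory chain (0.06, 0.0830) and T and NK cell genes (-0.11, 0.135). Macrophage genes were not called without DMM_1wk replicate 2 (0.13, 0.148), whose list mean of -0.81 lay apart from the other 3 DMM arrays (0.09 to 0.20). Ribosomal genes were not called without DMM_1wk replicate 3 (0.933). With an estimated correlation the adjusted p-values of these 9 ran from 0.423 for T and NK cells to 0.859 for respiratory chain and ribosomal genes. Proteases and macrophages also missed the threshold with slide as a block (adjusted p = 0.0574 for both). The same 2 lists were not called without sham_6wk replicate 2 in the shared fit (camera adjusted p = 0.0743 and 0.1185). Not called were osteoclast (-0.03), TGF-beta and BMP (0.02), tendon (0.08), inflammatory mediators (-0.13), interferon (-0.04), erythroid (-0.06), muscle (0.04), nerve and Schwann cell (0.09) and cell cycle (-0.07) genes, nor the immediate early (0.01), hypoxia (-0.02) and stromal reticular (0.04) lists. Single arrays decided some of these too. Osteoclast genes were called lower without DMM_1wk replicate 1 (-0.23, 0.00120) and higher without DMM_1wk replicate 2 (0.24, 0.0153), as were TGF-beta and BMP genes (-0.11, 0.0468, and 0.14, 2.07e-04). Erythroid genes were called higher without DMM_1wk replicate 2 (0.36, 6.50e-05) and lower without DMM_1wk replicate 3 (-0.31, 3.40e-04). In all, 15 of 27 lists were called (11 higher, 4 lower), 13 with slide as a block, and 0 with an estimated correlation or by fry. The medians of all 15 moved over 1.5 times with 1 array left out. Adjusted over each list alone, 0 members passed. Simulated data with no effect gave a median of 9.5 calls, but without the slide balance of the real groups.

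**Figure D1:**
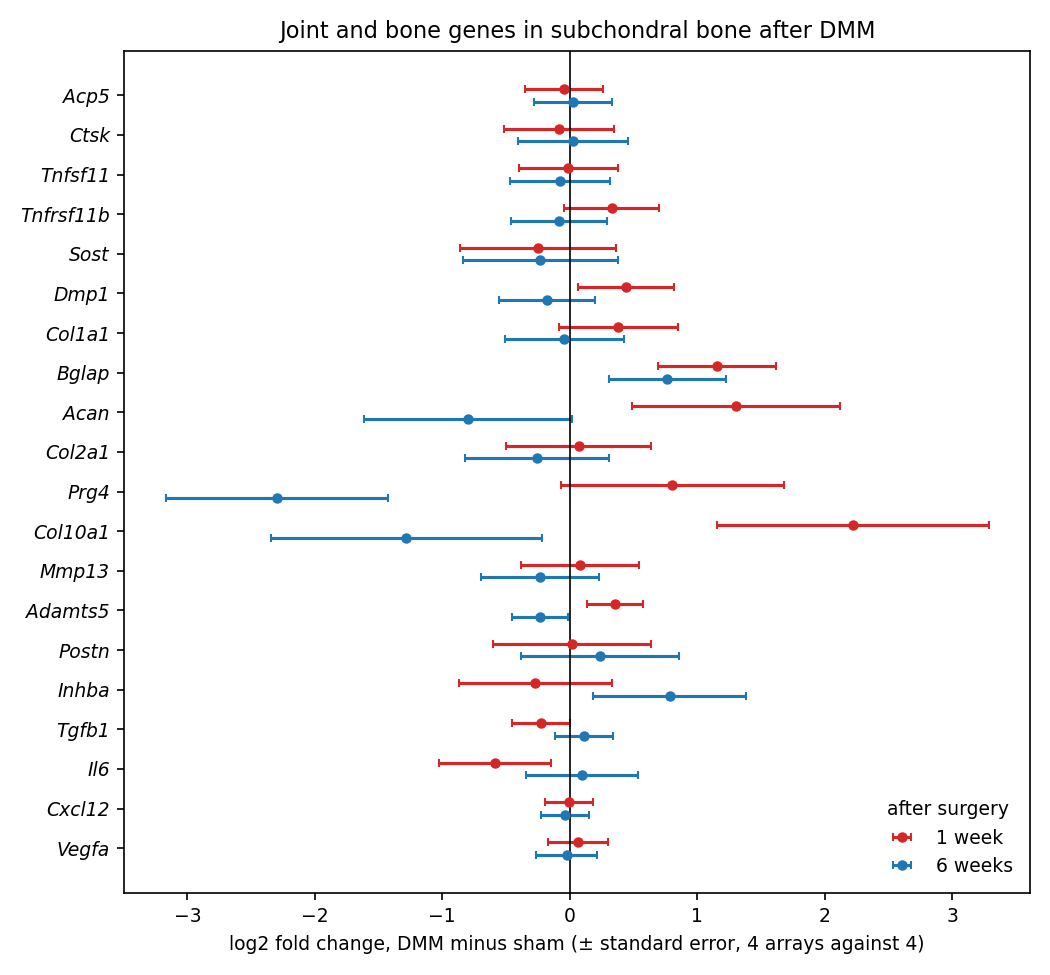
Log2 difference between DMM and sham (x axis; bars show the standard error, 4 arrays against 4) for joint and bone genes at 1 week (red) and 6 weeks (blue). Bglap is higher at both times (1.16 and 0.77), and Prg4 is lower at 6 weeks (-2.30).

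What was different 6 weeks after destabilization? Prg4, which encodes the lubricant lubricin, was lower than in sham bone (-2.30 ± 0.87, with sham at -0.84 ± 0.84 SD and DMM at -3.13 ± 1.64, n = 4 each) on 4 of 4 arrays. It was lower within both slides (-3.10 and -1.49), without passing the threshold (limma adjusted p = 1.0). Bglap was again higher, by 0.77 ± 0.46 (sham 6.46 ± 0.61 SD, DMM 7.23 ± 0.24) on 4 of 4 arrays, and by 0.52 and 1.01 within slides. The cartilage genes Col10a1 (-1.28 ± 1.07), Acan (-0.80 ± 0.82) and Col2a1 (-0.26 ± 0.57) had lower means after DMM, but within slides Col10a1 gave -3.32 and 0.76 and Acan -2.16 and 0.56. Inhba had a higher mean by 0.78 ± 0.60 (1.95 and -0.38 within slides). These means depended on single arrays: without sham_6wk replicate 2 Col10a1 gave -0.36, Acan -0.32, Col2a1 0.18 and Inhba -0.07, while Bglap gave 0.85, and without DMM_6wk replicate 2 Acan gave -0.14. Resorption and bone matrix genes had mean differences near 0 or lower: Acp5 0.02 ± 0.31, Ctsk 0.03 ± 0.43, Col1a1 -0.04 ± 0.47, Tnfsf11 -0.08 ± 0.39, Tnfrsf11b -0.08 ± 0.38, Sost -0.23 ± 0.61 and Dmp1 -0.18 ± 0.38. These hid opposite values: Col1a1 ran from -1.17 to 1.09 over the alternatives (7 of 21 changed sign), and without sham_6wk replicate 2 it was 0.40 and Sost -0.82. Among proteases and signals, Mmp13 stood at -0.23 ± 0.46, Adamts5 at -0.23 ± 0.22, Tgfb1 at 0.11 ± 0.23, Postn at 0.23 ± 0.62 (lowest probe -0.33) and Il6 at 0.10 ± 0.44. Cxcl12 (-0.04 ± 0.19) and Vegfa (-0.03 ± 0.24) were near 0. With 1 array left out 20 of the 21 genes moved over 1.5 times and 16 changed sign. Of the 21 genes, 7 were higher and 14 lower and none passed over the 21 alone (lowest adjusted p = 0.399).

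At 6 weeks limma called 0 of 28250 genes, and 220 had an unadjusted p under 0.05 (61 higher, 159 lower). The genes with the smallest unadjusted p, again not past the threshold (adjusted p = 1.0 for each), were higher for Elobl (1.19 ± 0.35), the segmentation factor Mesp2 (0.87 ± 0.29), Ldc1 (0.77 ± 0.26), Cabcoco1 (1.07 ± 0.37) and the arginase Arg2 (0.80 ± 0.29). They were lower for Tmem213 (-1.49 ± 0.34), the fatty acid receptor Ffar1 (-1.14 ± 0.27) and the vomeronasal receptor Vmn1r167 (-1.14 ± 0.36). The odorant receptors Olfr1195 and Olfr10 were above background on 0 of 4 DMM arrays. With undetected values set to the floor, their means on these arrays were at least 2.07-fold and 2.46-fold lower, a bound without sampling error. Without sham_6wk replicate 2 they gave -2.20 and -1.11. Over the alternatives Olfr1195 ran from -2.84 to -0.67 and Olfr10 from -1.78 to -0.44. Groups did not overlap for 141 genes (0.499%, against 2.86% for freely exchanged arrays, which again leaves out the slide balance).

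Lists called higher at 6 weeks after DMM held genes of the respiratory chain, cell division, ribosomes and marrow cells, and none of these 7 lists was called higher without sham_6wk replicate 2. Respiratory chain (median 0.24, 33 of 35 higher), cell cycle (0.29, 29 of 30) and ribosomal protein genes (0.18, 36 of 40) each had a camera adjusted p of 1.07e-06, and 0.858 with an estimated correlation. Examples were the mitotic genes Prc1 (0.33 ± 0.22, lowest of 5 probes -0.28), Nusap1 (0.60 ± 0.42) and Cdk1 (0.81 ± 0.58) and the thymidylate synthase Tyms (0.54 ± 0.38, lowest probe -0.03). In the respiratory chain Ndufa9 (0.35 ± 0.25), Atp5b (0.41 ± 0.30) and Cox7a2 (0.36 ± 0.27) were higher and Sdhc (-0.25 ± 0.15) lower. Among ribosomal genes Rpl7 (0.67 ± 0.49, lowest probe -0.11), Rps3 (0.31 ± 0.24), Rps14 (0.46 ± 0.36) and Rps7 (0.42 ± 0.34) were higher. Values without sham_6wk replicate 2 included Nusap1 0.04, Cdk1 0.09, Tyms 0.07, Ndufa9 0.06, Atp5b 0.02, Cox7a2 0.03, Rpl7 0.06, Rps3 0.04, Rps14 0.03 and Rps7 0.03. Neutrophil genes (0.24, adjusted p = 2.26e-04, or 0.858 with an estimated correlation) included Stfa2l1 (0.85 ± 0.47), lactoferrin Ltf (0.53 ± 0.32), Itgb2l (0.66 ± 0.43) and S100a8 (0.35 ± 0.23). Erythroid genes (0.30, adjusted p = 5.40e-04, or 0.858 with an estimated correlation) included the haemoglobin chaperone Ahsp (0.93 ± 0.69), Rhd (0.69 ± 0.52) and Epb42 (0.98 ± 0.75). The same omission gave Stfa2l1 0.31, Ltf 0.19, Itgb2l 0.11, S100a8 0.14, Ahsp 0.16, Rhd 0.16 and Epb42 0.10. Macrophage (0.25) and interferon genes (0.15) were higher as well (0.858 and 0.973 with an estimated correlation). Chondrocyte genes were lower in 24 of 29 (median -0.65, adjusted p = 5.70e-05, or 0.858 with an estimated correlation). Examples were the Wnt antagonist Frzb at -1.0 ± 0.62, the cartilage regulator Sox9 at -0.80 ± 0.50 and Chad at -0.65 ± 0.51. Without sham_6wk replicate 2 Frzb gave -0.83, Sox9 -0.33 and Chad -0.36. Over the alternatives Frzb ran from -2.69 to 0.68, Sox9 from -2.13 to 0.53 and Chad from -1.66 to 0.35. Adipocyte genes were lower too (median -0.15, adjusted p = 0.0275, or 0.858 with an estimated correlation). Of these 9 lists adipocyte alone had the same sign in both slides (-0.17 and -0.33), but it was not called without DMM_6wk replicate 1 (-0.07, 0.244), DMM_6wk replicate 2 (-0.16), sham_6wk replicate 3 (-0.11, 0.843) or sham_6wk replicate 4 (-0.20, 0.486): chondrocyte genes gave -1.75 and 0.47, cell cycle genes 0.83 and -0.27. The list means of sham_6wk replicate 2, on slide 1, were -0.94 for cell cycle and -0.81 for the respiratory chain, where the other 3 sham arrays gave 0.26 to 0.44 and 0.09 to 0.18. Without it cell cycle genes gave -0.03 (adjusted p = 0.491) and ribosomal genes 0.02 (0.871). Interferon genes were then called lower (-0.16, 3.64e-05), and chondrocyte genes were not called (-0.25, 0.218). Leaving out DMM_6wk replicate 2 ended the call of chondrocyte (-0.07, 0.335), interferon (0.08, 0.245) and macrophage genes (0.20, 0.0629), and leaving out DMM_6wk replicate 1 that of interferon (0.283) and macrophage genes (0.10, 0.277). None of the 9 lists was called with each of the 8 arrays left out, and the medians of all 9 moved over 1.5 times. Calls were 9 with slide as a block and 0 with an estimated correlation or by fry, with 0 members past the threshold over their list alone.

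Did the effect of DMM differ between 1 and 6 weeks, and what did both times share? Adipocyte genes had medians of opposite sign at the 2 times (0.20 and -0.15), and 17 of 22 had a lower DMM effect at 6 weeks (median change -0.30, camera adjusted p = 3.87e-06, or 0.540 with an estimated correlation). The change was -3.35 ± 1.18 for Cfd, -2.34 ± 0.77 for Plin4, -2.73 ± 1.11 for Cidec and -2.01 ± 0.86 for Adig. Chondrocyte genes were lower in 26 of 29 (median -0.69, adjusted p = 1.42e-06, or 0.540 with an estimated correlation). The members were led by Prg4 (-3.10 ± 1.24), Col10a1 (-3.50 ± 1.51), Frzb (-1.99 ± 0.88) and Cilp (-2.40 ± 1.24). Neutrophil genes moved the other way in 23 of 24 (median 0.42, adjusted p = 6.51e-08, or 0.540 with an estimated correlation): Cxcr2 (0.74 ± 0.37), Stfa2l1 (1.33 ± 0.66), Itgb2l (1.05 ± 0.60) and Chil3 (0.73 ± 0.46). Platelet genes did so in 17 of 18 (median 0.66, adjusted p = 1.42e-06, or 0.540 with an estimated correlation), with the receptors Clec1b (0.93 ± 0.56), Gp1bb (0.80 ± 0.50), Gp1ba (0.87 ± 0.54) and Gp9 (0.70 ± 0.44). Cell cycle genes (median 0.36, adjusted p = 1.72e-06, or 0.593 with an estimated correlation) included Pcna (0.79), Tyms (0.57), Prc1 (0.44, lowest probe -0.32) and Cenpf (0.40). Over the alternatives Pcna ran from -0.31 to 1.90, Tyms from -0.21 to 1.35, Prc1 from 0.03 to 0.85 and Cenpf from 0.15 to 0.65. The cell cycle list was not called without sham_6wk replicate 2 (0.04, adjusted p = 0.83). Macrophage genes (median 0.31, adjusted p = 2.39e-04, or 0.540 with an estimated correlation) included the marrow macrophage receptors Timd4 (1.89 ± 0.99), Cd163 (0.99 ± 0.70) and Vsig4 (0.82), against Marco (-0.86), and without that array this list was not called either (0.08, adjusted p = 0.531). The called lists with the same sign in both slides were adipocyte (-0.43 and -0.33), neutrophil (0.64 and 0.15), platelet (0.87 and 0.41) and T and NK cell (0.34 and 0.01), while chondrocyte genes gave -2.33 and 0.42. Of the 33 genes the rule picked here, 13 moved over 1.5 times with 1 array left out and 0 changed sign. In the other alternatives 6 of 387 values changed sign. Frzb ran from -4.265 to 0.287, Timd4 from -0.185 to 3.148 and Vsig4 from -0.437 to 1.619, while Col10a1 ran from -6.727 to -0.28. Over the alternatives Cxcr2 ran from 0.44 to 0.98, Stfa2l1 from 0.60 to 2.05, Itgb2l from 0.11 to 2.00 and Chil3 from 0.04 to 1.41.

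Limma called 0 genes for the change of the DMM effect, with 193 at an unadjusted p under 0.05. Closest, but not past the threshold (adjusted p = 1.0 for each), were the melanocyte gene Mlana (0.89 ± 0.28), Ldc1 (1.15 ± 0.37), Cfap100 (0.86 ± 0.28, other probe -0.80), Penk (0.82 ± 0.27) and Tex52 (1.60 ± 0.55). In the other direction were Tmem213 (-1.72 ± 0.47), Cyp2f2 (-3.35 ± 1.00, and -3.31 and -3.39 within slides), the muscle gene Myoz2 (-3.29 ± 1.05), the neuroendocrine factor Insm1 (-1.69 ± 0.55) and Plin4. Erythroid (0.36), respiratory chain (0.17), interferon (0.15) and T and NK cell genes (0.12) were also called higher, and fibrous matrix (-0.39), osteocyte (-0.34), Wnt (-0.23) and endothelial genes (-0.16) lower, at 0.540 to 0.708 with an estimated correlation. Without sham_6wk replicate 2 erythroid genes were not called (0.10, adjusted p = 0.537), and interferon (-0.10, 0.00995) and respiratory chain genes (-0.08, 0.0212) were called in the other direction, while B cell (-0.23, 0.00898), stromal reticular (-0.22, 0.0212) and ribosomal genes (-0.07, 0.0253) were newly called lower. Several other omissions called ribosomal genes higher instead, such as sham_6wk replicate 4 (0.18, camera adjusted p = 0.00109) and DMM_1wk replicate 3 (0.17, 0.00112). Osteoblast genes were newly called lower in several omissions, such as DMM_1wk replicate 2 (-0.29, 5.38e-04) and DMM_6wk replicate 3 (-0.49, 0.00170). Leaving out DMM_1wk replicate 1 ended the call of osteocyte (-0.06, camera adjusted p = 0.763), fibrous matrix (-0.13, 0.210), Wnt (0.0946), endothelial (-0.01, 0.710) and T and NK cell genes (0.08, 0.210). Adipocyte, chondrocyte, neutrophil and platelet genes were called with each of the 16 arrays left out. Of the others, the osteocyte list lost its call in 9 of 16 omissions, T and NK cell and interferon genes in 6, endothelial and respiratory chain genes in 5 and fibrous matrix and erythroid genes in 3. The medians of all 14 moved over 1.5 times. In all 14 of 27 lists were called (8 higher, 6 lower), 14 with slide as a block, and 0 with an estimated correlation or by fry. Over each list alone 0 members passed. Across genes the DMM effects at 1 and 6 weeks had a correlation of -0.01 (50.7% of the same sign), with genes not being independent replicates.

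Averaged over both times, Nupr1 was higher by 0.74 ± 0.19 on 8 of 8 arrays (0.72 and 0.77 within slides), although its other probe gave -0.07. Bglap was higher by 0.96 ± 0.33 on 7 of 8 (0.66 and 1.26), neither past the threshold (adjusted p = 1.0). Also not past it were Prm1 (1.26 ± 0.36), Cib3 (0.44 ± 0.14), the angiopoietin-like gene Angptl2 (1.19 ± 0.39) and Elobl (0.72 ± 0.24) on the higher side. Lower were Izumo2 (-0.89 ± 0.26), Syt13 (-0.66 ± 0.21), Ffar1 (-0.58 ± 0.19) and the blood cell factors Gata3 (-0.41 ± 0.13, 8 of 8 arrays) and Gata2 (-0.54 ± 0.18, 7 of 8). Osteoblast genes were higher in 22 of 25 (median 0.15, camera adjusted p = 3.01e-04, or 0.965 with an estimated correlation), with Bglap2 (0.60 ± 0.26), Ifitm5 (0.62 ± 0.30) and Cgref1 (0.63 ± 0.35), but this list was not called without DMM_6wk replicate 3 (0.03, adjusted p = 0.113). Fibrous matrix genes were higher in 31 of 36 (median 0.25, adjusted p = 3.31e-06, or 0.965 with an estimated correlation), with decorin Dcn (0.61 ± 0.27), Tnn (1.08 ± 0.57), Cthrc1 (0.72 ± 0.41) and Loxl2 (0.30 ± 0.18). Platelet genes were lower in 18 of 18 (median -0.22, adjusted p = 2.00e-06, or 0.965 with an estimated correlation, -0.27 and -0.19 within slides). This average came from 1 week (median -0.58): at 6 weeks 9 platelet genes were higher and 9 lower (median 0.04). They included Mmrn1 (-0.50 ± 0.21), Rab27b (-0.46 ± 0.22), Treml1 (-0.35 ± 0.22) and Gp5 (-0.39 ± 0.24). B cell genes (median 0.14) were higher, with Rag1 (0.56 ± 0.37), Fcrla (0.39), Cd79b (0.33) and Vpreb3 (0.28). Ribosomal (median 0.13, with Rpl11 0.14 and -0.01 on its other probe, Rps3 0.20, Rpl3 0.20, Rpl22 0.18) and respiratory chain genes (median 0.15, with Uqcrq 0.23, Ndufa9 0.26, Atp5o 0.16, Ndufv1 0.24) were higher too. So were cell cycle (0.11) and erythroid genes (0.16), each list of these 5 at 0.965 with an estimated correlation. These 5 lists were not called without sham_6wk replicate 2: cell cycle -0.04 (adjusted p = 0.197), erythroid 0.03 (0.771), respiratory chain 0.04 (0.244), ribosomal 0.04 (0.192) and B cell 0.12 (0.244). Interferon genes were then called lower (-0.10, 3.11e-04), while osteoblast (0.35), fibrous matrix (0.31) and platelet genes (-0.30) were still called. In contrast, interferon genes were called higher without sham_6wk replicate 3 (0.13, 0.00184) or DMM_6wk replicate 3 (0.10, 0.0109). Limma called 0 genes (265 at an unadjusted p under 0.05), and 8 lists were called, of which fibrous matrix and platelet genes alone were called with each of the 16 arrays left out, 8 with slide as a block and 0 with an estimated correlation or by fry.

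**Figure D2:**
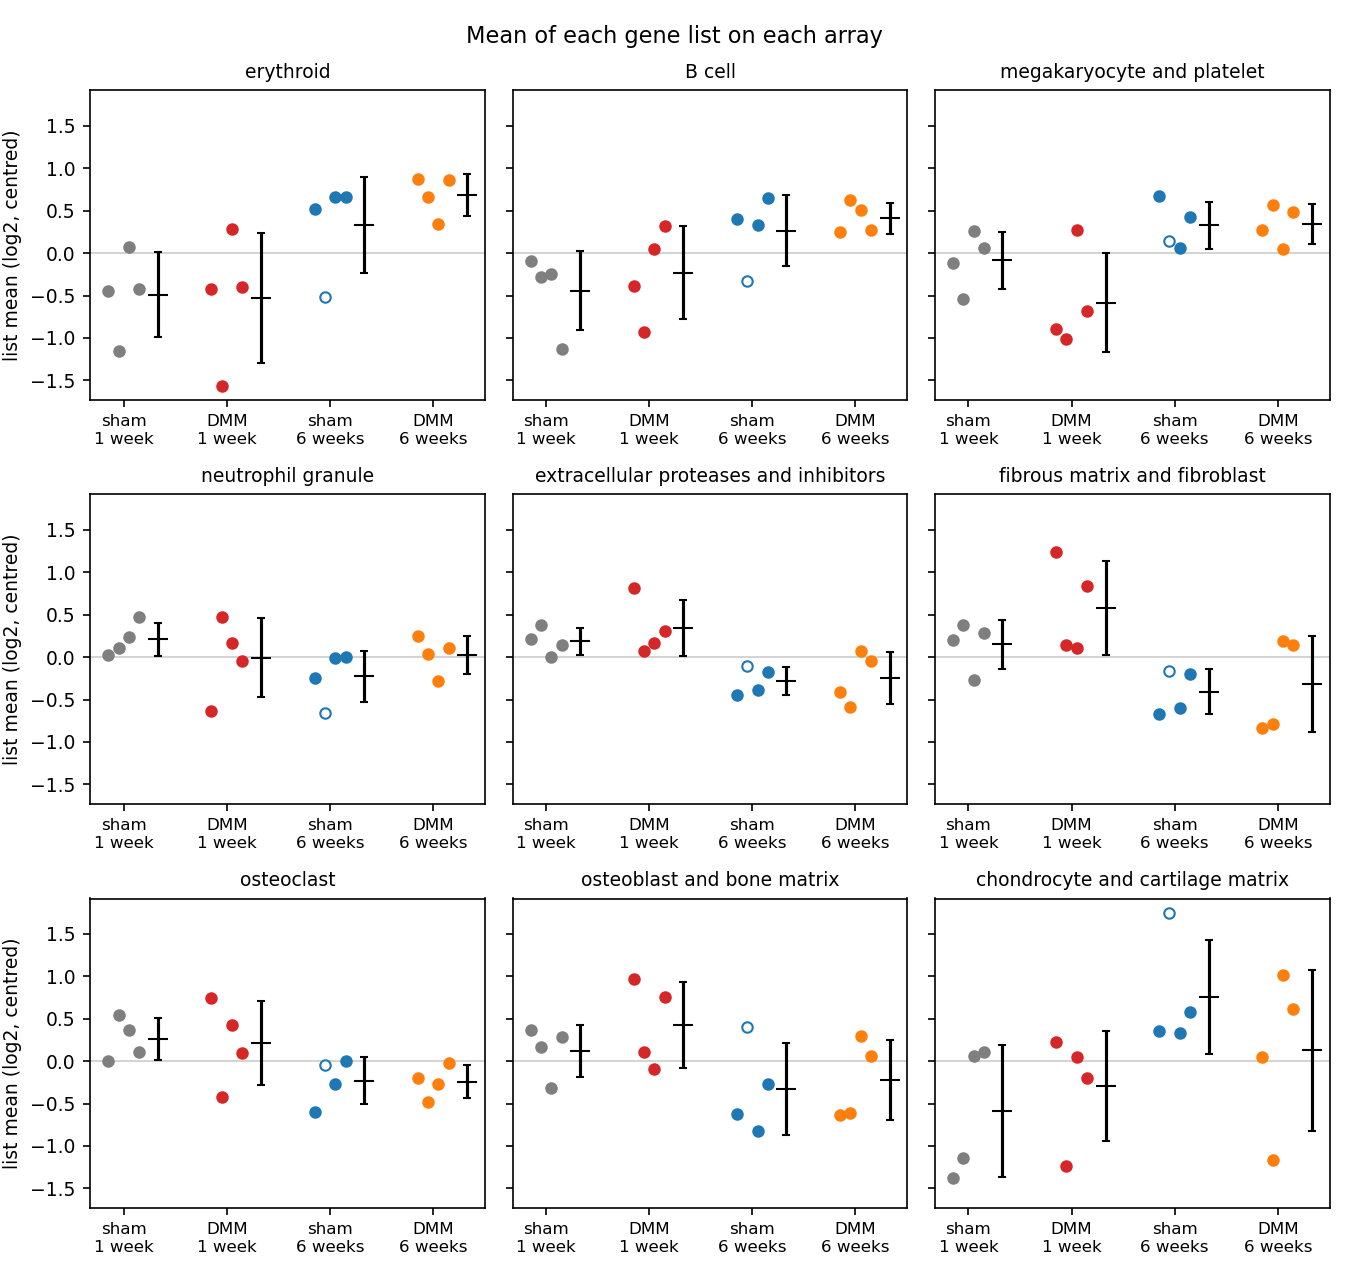
Mean of 9 gene lists on each array (y axis, log2 centred on the mean of all arrays), by group, with the group mean and SD in black and sham_6wk replicate 2 as an open circle. Erythroid and B cell means lie higher at 6 weeks in both surgery groups, and the open circle has the highest chondrocyte mean (1.75).

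How did subchondral bone differ between 1 and 6 weeks after sham surgery? The gelatinase Mmp9 of osteoclasts and neutrophils was lower at 6 weeks (-0.94 ± 0.17, and -0.99 and -0.89 within slides), without passing the threshold over all genes (limma adjusted p = 0.585, as for the next 9 genes, each on 4 of 4 arrays). Other lower genes were the histone demethylase Kdm6b (-1.13 ± 0.21), Samd12 (-1.52 ± 0.31), the phospholipase Pla2g7 (-0.86 ± 0.18) and N4bp1 (-0.65 ± 0.14). Higher, also not past the threshold, were the liver P450 gene Cyp2e1 (1.28 ± 0.23), Olfr1495 (1.61 ± 0.33), the calcium channel Cacna1g (0.78 ± 0.17), the protease inhibitor Serpina1c (3.69 ± 0.83) and Cyp2f2 (3.07 ± 0.71). Limma called 0 genes and 2020 had an unadjusted p under 0.05. Groups did not overlap for 1506 (5.33%, against 2.86% for freely exchanged arrays, which leaves out the slide balance).

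Erythroid genes were higher at 6 weeks in 25 of 25 members after sham (median 0.88, camera adjusted p = 9.29e-12, or 0.227 with an estimated correlation). Among them were the haem synthesis genes Alas2 (1.16 ± 0.39) and Fech (1.05 ± 0.34), the regulator Tal1 (0.92 ± 0.29) and Tspo2 (1.07 ± 0.25). B cell genes were higher in 20 of 21 (median 0.75, adjusted p = 7.13e-11, or 0.222 with an estimated correlation). Leading members were the receptor genes Cd79a (0.99 ± 0.30) and Cr2 (0.86 ± 0.26) and the factor Spib (0.77 ± 0.24). Chondrocyte genes were higher in 24 of 29 (median 1.42, adjusted p = 9.49e-09, or 0.238 with an estimated correlation, and 2.55 and 0.19 within slides): Chad 2.06 ± 0.51, Col10a1 3.57 ± 1.07, Cytl1 3.63 ± 1.17 and Cnmd 2.64 ± 0.88. Without sham_6wk replicate 2 the median was 1.18, still called (camera adjusted p = 4.67e-04). That array had the highest level of Col10a1 (3.09, others up to 1.08). Over the alternatives Chad ran from 1.20 to 2.91, Col10a1 from 1.92 to 5.22, Cytl1 from 2.38 to 4.89 and Cnmd from 0.92 to 4.35. Proteases and inhibitors were lower in 28 of 32 (median -0.53, adjusted p = 9.49e-09, or 0.155 with an estimated correlation). Lower members included Timp1 (-1.02 ± 0.31) and the urokinase receptor Plaur (-0.78 ± 0.31), against Timp4 (0.92 ± 0.30). Interferon genes were lower in 29 of 31 (median -0.33, adjusted p = 5.72e-08, or 0.288 with an estimated correlation), but without sham_6wk replicate 2 they were not called (median -0.02, adjusted p = 0.274). They held the antiviral genes Oas2 (-1.41 ± 0.34), Oasl2 (-1.04 ± 0.26), Oas1a (-1.19 ± 0.32) and Bst2 (-0.40 ± 0.16). Neutrophil genes were lower in 22 of 24 (median -0.43, adjusted p = 7.56e-08, or 0.238 with an estimated correlation), with Cxcr2 at -1.03 ± 0.26, Padi4 at -0.82 ± 0.31 and Mmp8 at -0.63 ± 0.33. The neutrophil median was -0.19 without sham_6wk replicate 2, still called (0.00143).

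Lower after sham at 6 weeks were also osteoclast (median -0.47), fibrous matrix (-0.49), osteoblast (-0.45), osteocyte (-0.41), TGF-beta and BMP (-0.30), hypoxia (-0.25), immediate early (-0.26), macrophage (-0.20), inflammatory (-0.18) and endothelial genes (-0.19). Adipocyte (0.42), platelet (0.41), muscle (0.40), cell cycle (0.16) and ribosomal genes (0.12) were higher. Without sham_6wk replicate 2 the macrophage (adjusted p = 0.887), inflammatory (0.0970) and endothelial lists (0.505) were not called, and respiratory chain genes were called higher (0.18, camera adjusted p = 7.02e-04). The medians of the higher lists were then 0.87 for adipocyte, 0.57 for platelet, 0.18 for muscle, 0.46 for cell cycle and 0.30 for ribosomal genes. Respiratory chain genes were called lower instead without sham_6wk replicate 1 (-0.13, 0.0443), sham_6wk replicate 3 (-0.17, 0.0237) or sham_6wk replicate 4 (-0.18, 0.00635). The same held without sham_1wk replicate 1 (-0.13, 0.0174), so the direction of this list depended on the array left out. Cell cycle (0.02, 0.882) and ribosomal genes (0.03, 0.620) were not called without sham_6wk replicate 4. With an estimated correlation these 15 lists had adjusted p-values from 0.140 for hypoxia, immediate early and inflammatory genes to 0.673 for cell cycle genes. In all 21 of 27 lists were called (8 higher, 13 lower), 20 with slide as a block (endothelium adjusted p = 0.0508), and 0 with an estimated correlation or by fry. Over each list alone 19 members passed, most for adipocyte (5) and B cell genes (4).

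How did it differ between the same times after DMM? Erythroid genes were higher at 6 weeks in 25 of 25 (median 1.31, camera adjusted p = 1.58e-18, or adjusted p = 0.140 with an estimated correlation and 0.0359 by fry). Over the list alone 22 passed, and the medians were 1.88 and 0.69 within slides. They included Tspo2 (1.09 ± 0.25), Fech (1.31 ± 0.34), Alas2 (1.44 ± 0.39) and the erythropoietin receptor Epor (1.30 ± 0.37). Platelet genes were higher in 17 of 18 (median 1.09, adjusted p = 3.14e-14, or 0.140 with an estimated correlation and 0.0359 by fry): Gp9 1.29 ± 0.31, Treml1 1.19 ± 0.31, Gp5 1.31 ± 0.34 and the chemokine Ppbp 1.14 ± 0.31. Fibrous matrix genes were lower in 34 of 36 (median -0.83, adjusted p = 3.14e-14, or 0.140 with an estimated correlation). Examples were the pericellular collagens Col6a1 (-1.54 ± 0.37) and Col6a2 (-1.58 ± 0.39), Col8a1 (-1.47 ± 0.38) and Col12a1 (-1.70 ± 0.45). Proteases and inhibitors were lower in 25 of 32 (median -0.66, adjusted p = 1.71e-10, or 0.140 with an estimated correlation and 0.0359 by fry). They included the aggrecanases Adamts4 (-1.60 ± 0.36) and Adamts5 (-0.88 ± 0.22), Timp1 (-1.34 ± 0.31) and Mmp9 (-0.66 ± 0.17). Cell cycle genes were higher in 29 of 30 (median 0.51, adjusted p = 1.44e-10, or 0.259 with an estimated correlation), with Rrm2 (0.61 ± 0.19), Prc1 (0.66 ± 0.22, lowest probe -0.07), Birc5 (0.56 ± 0.19) and Ccna2 (0.51 ± 0.18). Osteoblast genes were lower in 23 of 25 (median -0.66, adjusted p = 1.55e-08, or 0.206 with an estimated correlation). Members included the parathyroid hormone receptor Pth1r (-1.09 ± 0.34), Fkbp11 (-1.15 ± 0.42), Runx2 (-0.77 ± 0.29) and Creb3l1 (-1.39 ± 0.57).

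No single gene passed the threshold between the times after DMM: limma called 0, and 2741 had an unadjusted p under 0.05. Groups did not overlap for 1477 (5.23%, against 2.86% for freely exchanged arrays, which leaves out the slide balance). Closest (adjusted p = 0.256 and 4 of 4 arrays for each) were Mesp2 (1.56 ± 0.29), Urah (1.30 ± 0.24), Shisa9 (2.14 ± 0.41), Erfl (1.43 ± 0.28) and the histone H2ac6 (1.16 ± 0.23) on the higher side. Lower were Spsb4 (-1.15 ± 0.22), Oas2 (-1.66 ± 0.34) and the nuclear receptor Nr4a2 (-1.77 ± 0.38). Ccdc146 was above background on 0 of 4 arrays at 6 weeks. With those values set to the floor its mean was at least 1.68-fold lower, a bound without sampling error. Over the alternatives it ran from -2.33 to -0.24. Further lists were called lower (osteocyte -0.68, osteoclast -0.56, Wnt -0.44, endothelium -0.38, TGF-beta and BMP -0.27, immediate early -0.21, interferon -0.18, hypoxia -0.08) or higher (B cell 0.69, muscle 0.41, ribosomal 0.22, T and NK cell 0.13). Their adjusted p-values with an estimated correlation ran from 0.140 for immediate early genes to 0.543 for interferon genes. Interferon (-0.08, camera adjusted p = 0.294) and hypoxia genes (-0.06, 0.0519) were not called without DMM_6wk replicate 3. T and NK cell genes were not called without DMM_1wk replicate 1 (0.10, 0.144), DMM_1wk replicate 2 (0.17, 0.196) or DMM_6wk replicate 1 (0.11, 0.124). In all 18 lists were called (7 higher, 11 lower), 18 with slide as a block, 4 by fry and 0 with an estimated correlation, and 70 members passed over their list alone. The chondrocyte list, higher after sham, was not called after DMM (0.26), but without DMM_6wk replicate 2 it was called higher (0.79, camera adjusted p = 3.18e-04).

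Which genes changed between 1 and 6 weeks whichever surgery was done? This comparison of 8 arrays against 8 was added after seeing the data. Limma called 247 genes (181 rose, 66 fell, lowest adjusted p = 0.0347), 169 of them with a gene symbol, where 4455 had an unadjusted p under 0.05. This count was 0 with median scaling, with no filter on dim probes and when any 1 of 10 of the 16 arrays was left out, and 1502 without sham_6wk replicate 2, so the changes given next depend on which arrays are kept. Oas2, an interferon-induced antiviral enzyme, fell by 1.54 (-1.54 ± 0.24, adjusted p = 0.0347, 8 of 8 arrays, -2.19 and -0.88 within slides). Mmp9, the gelatinase of osteoclasts and neutrophils, fell by 0.80 (-0.80 ± 0.12, adjusted p = 0.0347, 8 of 8), by -0.91 and -0.69 within slides and by -0.79 on its other probe. The metalloprotease inhibitor Timp1 fell by 1.18 (-1.18 ± 0.22, adjusted p = 0.0347, 8 of 8, -1.37 and -0.99 within slides). The aggrecanase Adamts4 (-1.25 ± 0.25, adjusted p = 0.0396), the nuclear receptor Nr4a2 (-1.47 ± 0.27, 0.0347) and the collagens Col6a1 (-1.29 ± 0.26, 0.0401), Col6a2 (-1.26 ± 0.28, 0.0472) and Col12a1 (-1.43 ± 0.32, 0.0486) also fell on 8 of 8 arrays. Ccdc146 (-1.23 ± 0.23) and Prdm8 (-1.53 ± 0.32) fell near the background, above it on 0 of 4 DMM arrays at 6 weeks, so that their fold depends on the floor. Serpina1a, which encodes the protease inhibitor alpha-1-antitrypsin, rose by 3.58 ± 0.63 (adjusted p = 0.0347, 8 of 8, 3.99 and 3.17 within slides). So did Serpina1d (3.44 ± 0.61), Serpina1c (3.27 ± 0.58) and Serpina1b (1.81 ± 0.33), near-identical genes. Whether the probes tell these copies apart was not analysed here. The cartilage and bone matrix protein Chad (1.68 ± 0.36, adjusted p = 0.0443, 1.76 and 1.61 within slides), Unc93a2 (2.43 ± 0.53, 0.0467), the proline transporter Slc6a20a (1.71 ± 0.34, 0.0390) and Cplx3 (1.67 ± 0.34, 0.0404) rose on 8 of 8.

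Erythroid genes were higher at 6 weeks in 25 of 25 (median 1.08, camera adjusted p = 1.26e-17, or 0.156 with an estimated correlation and 0.0128 by fry). Of these 4 rose past the threshold: Tspo2 (1.08 ± 0.17, adjusted p = 0.0347), Fech (1.18 ± 0.24, 0.0401), Alas2 (1.30 ± 0.27, 0.0434) and Tal1 (0.93 ± 0.20, 0.0472), each on 8 of 8 arrays. Over the list alone 23 passed. B cell genes were higher in 20 of 21 (median 0.69, adjusted p = 5.12e-11, or 0.156 with an estimated correlation and 0.0227 by fry, and 0.68 and 0.71 within slides). Spib (0.80 ± 0.17, adjusted p = 0.0443) and the surface antigen Ms4a1 (1.35 ± 0.30, 0.0490, 7 of 8 arrays) rose. Cd79a (0.85, 0.0632) was not past the threshold. Platelet genes were higher in 17 of 18 (median 0.76, adjusted p = 5.12e-11, or 0.156 with an estimated correlation and 0.0227 by fry). Gp9 (0.94 ± 0.22, 0.0542), Gata1 (1.00 ± 0.25, 0.0629), Treml1 (0.86, 0.0678) and Gp5 (0.95, 0.0696) did not pass over all genes and 15 passed over the list alone. Fibrous matrix genes were lower in 34 of 36 (median -0.68, adjusted p = 1.82e-12, or 0.156 with an estimated correlation and 0.0232 by fry), 3 past the threshold over all genes and 13 over the list, with Col8a1 (-1.18 ± 0.27, 0.0515) outside. Proteases and inhibitors were lower in 28 of 32 (median -0.61, adjusted p = 2.72e-11, or 0.149 with an estimated correlation and 0.0110 by fry), 18 past over the list, with Adamts5 (-0.59 ± 0.16, 0.0770) not past over all genes. Osteoblast genes were lower in 23 of 25 (median -0.55, adjusted p = 3.99e-08, or 0.225 with an estimated correlation), 9 past over the list and 0 over all genes. The closest were Pth1r (-0.92 ± 0.24, 0.0733), Fkbp11 (-1.10 ± 0.30, 0.0805), the alkaline phosphatase Alpl (-1.08 ± 0.31, 0.0943) and Creb3l1 (-1.23 ± 0.40, 0.134). Each of these 6 lists had the same sign within both slides.

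Osteoclast (median -0.47), osteocyte (-0.49), TGF-beta and BMP (-0.29), interferon (-0.28), immediate early (-0.19), hypoxia (-0.19), endothelial (-0.31), Wnt (-0.29) and neutrophil genes (-0.18) were lower at 6 weeks. Cell cycle (0.34), ribosomal (0.19), muscle (0.27), chondrocyte (0.82) and adipocyte genes (0.29, and -0.12 and 0.66 within slides) were higher. The neutrophil list was not called without sham_6wk replicate 2 (-0.10, camera adjusted p = 0.0773). Leaving out that array gave interferon -0.11 (still called, 0.0127), hypoxia -0.12, adipocyte 0.48 and cell cycle 0.51, and called respiratory chain genes higher (0.13, 0.00635). Adipocyte genes were not called in 5 of 16 omissions, among them sham_6wk replicate 3 (0.24, 0.154) and DMM_6wk replicate 3 (0.28, 0.123). With an estimated correlation these 14 lists had adjusted p-values from 0.149 for immediate early to 0.448 for ribosomal and adipocyte genes. Not called were inflammatory (-0.12), T and NK cell (0.13), stromal reticular (-0.03) and nerve and Schwann cell genes (0.04). Tendon (median 0.02), macrophage (0.01) and respiratory chain genes (0.02) were not called either on all 16 arrays, with a camera direction opposite to their median. The preset test called 20 of 27 lists (8 higher, 12 lower), 20 with slide as a block, 9 by fry and 0 with an estimated correlation, and 158 members passed over their list alone. The gene count was 645 with slide as a block and 0 within either slide alone (4 arrays against 4). The mice at 6 weeks were also older than those at 1 week, and harvest sessions are not given in the sources used here.

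**Figure D3:**
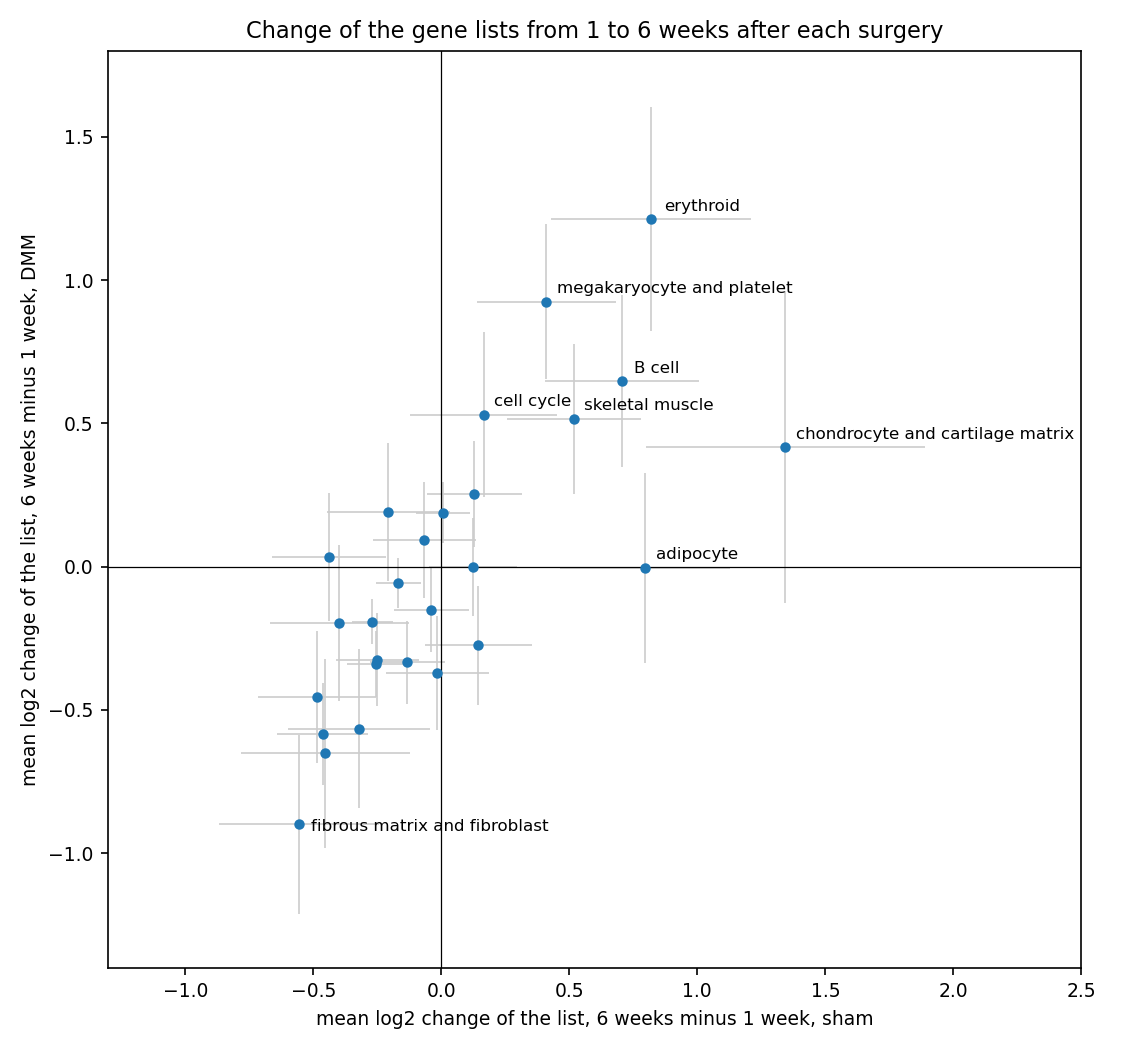
Mean log2 change of each of the 27 gene lists from 1 to 6 weeks after sham (x axis) and after DMM (y axis), with standard errors as grey bars. Erythroid genes have the highest mean after DMM (1.21) and fibrous matrix genes the lowest (-0.90), and chondrocyte genes the highest after sham (1.34). Without sham_6wk replicate 2 the median change after sham was 1.183 for chondrocyte and 1.215 for erythroid genes (1.418 and 0.879 with it).

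For reference, the probes of key genes lie at these 1-based positions of mm9: Bglap (NM_007541) on chromosome 3 from 88188307 to 88188366, Prg4 (NM_021400) on chromosome 1 from 152297067 to 152297126, and Nupr1 (NM_019738) on chromosome 7 from 133766978 to 133767037. Cfd (NM_013459) lies on chromosome 10 from 79355302 to 79355361, Col10a1 (NM_009925) on chromosome 10 from 34116831 to 34116890, and Cyp2f2 (NM_007817) on chromosome 7 from 27918570 to 27918629. Mmp9 (NM_013599) spans chromosome 2 from 164779091 to 164780300, Oas2 (NM_145227) lies on chromosome 5 from 121180343 to 121180402, and Col6a1 (NM_009933) on chromosome 10 from 76171538 to 76171597. Alas2 (NM_009653) lies on chromosome X from 147004993 to 147005052, Chad (NM_007689) on chromosome 11 from 94430136 to 94430195, and Serpina1a (NM_001252569) on chromosome 12 from 105091819 to 105091878.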

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

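Of the tests in this part, those of a label from another group, of cartilage in the piece and of the 6-week lists without 1 array were chosen after the results were seen.

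Dixon's test picked out 1 array in 14 of 204 groups of 4 values, where chance picks out about 1 in 20, or 10.2. In sham_6wk replicate 2 these were lower list means for erythroid (-0.52, others 0.52 to 0.66), stromal reticular (-0.17, others 0.02 to 0.04), cell cycle (-0.94, others 0.26 to 0.44) and respiratory chain genes (-0.81, others 0.09 to 0.18). The same array had a higher level of Acan (1.88, others -0.15 to 0.19) and a lower level of Inhba (-2.95, others 0.13 to 0.65). In DMM_1wk replicate 2 they were low macrophage (-0.81, others 0.09 to 0.20) and inflammatory list means (-0.14, others 0.08 to 0.09), a high muscle list mean (0.28, others -0.43 to -0.32) and a low Acan level (-1.28, others 0.18 to 0.44). The mean correlation of DMM_1wk replicate 2 with its group was 0.963 (others 0.975 to 0.977). Also apart were Tnfsf11 in DMM_1wk replicate 1 (-1.22, others -3.22 to -3.0), Postn in sham_1wk replicate 2 (1.16, others 0.35 to 0.44) and the 75th percentile of signal of DMM_6wk replicate 2 (812, others 471 to 516).

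By Dixon's test sham_6wk replicate 2 stood apart in erythroid, stromal reticular, cell cycle and respiratory chain genes, but not in osteoclast genes (-0.05, others -0.60 to 0.00). Without being picked out by that test, it also lay below the other sham 6-week arrays in further lists. These included interferon (-1.245, others 0.011 to 0.325), ribosomal (-0.577, others 0.043 to 0.262) and macrophage genes (-0.652, others -0.112 to 0.188). Its spread around its group among the brightest genes was 3.29 times the median of the other arrays, which argues against low signal as the whole cause. Its highest mean correlation with another group was 0.924, below the lowest value that any other array had with its own group (0.953), which argues against the label of another of these groups as the whole cause. Its mean correlation with its own group was lower still (0.911), and the value of 0.953 was itself lowered by this array (0.984 without it). A wrong label together with another cause stays open. Cartilage in the dissected piece stays open as a candidate explanation: this array was the highest of 16 for 18 of 29 chondrocyte genes (62.1%, exact 95% interval 42.3% to 79.3%, against 35.4% of all genes), of which the list shares 5 with other lists. The interval counts genes of 1 array as independent, although genes within lists were correlated (median estimate 0.342). It therefore measures no spread between replicates. The share of all genes was not matched for brightness, and 20 of the 29 were above background on all 16 arrays. Relative to the median of the other arrays Acan was higher by 1.95, Col2a1 by 1.55, Col9a1 by 3.06, Matn3 by 3.46 and Col10a1 by 4.41, but Comp by 0.10.

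Lists called between DMM and sham at 6 weeks rested on single arrays, and none of the 9 was called with each of the 8 arrays left out. Without sham_6wk replicate 2, 1 of the 9 lists, adipocyte, was called in the same direction (median -0.37), but it was not called without DMM_6wk replicate 1 (-0.07), DMM_6wk replicate 2 (-0.16), sham_6wk replicate 3 (-0.11) or sham_6wk replicate 4 (-0.20). Without DMM_6wk replicate 2 chondrocyte (-0.07), interferon (0.08) and macrophage genes (0.20) were not called, and without DMM_6wk replicate 1 neither were interferon (camera adjusted p = 0.283) and macrophage genes (0.277). Interferon genes were called in the other direction without sham_6wk replicate 2 (-0.16). Osteoblast genes were then called higher (0.40, camera adjusted p = 5.05e-04). The higher cell cycle, respiratory chain and erythroid means after DMM may therefore reflect this 1 sham array. Those 3 lists were not called among the remaining arrays.

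The test of the change of the DMM effect from 1 to 6 weeks picked out 14 gene lists by camera at the preset correlation, 0 of them with an estimated correlation (lowest adjusted p = 0.540). Medians were higher for platelet (0.66), neutrophil (0.42), erythroid (0.36), cell cycle (0.36), macrophage (0.31), respiratory chain (0.17), interferon (0.15) and T and NK cell genes (0.12). They were lower for chondrocyte (-0.69), fibrous matrix (-0.39), osteocyte (-0.34), adipocyte (-0.30), Wnt (-0.23) and endothelial genes (-0.16). Without sham_6wk replicate 2, adipocyte (-0.60), neutrophil (0.38), platelet (0.53), endothelial (-0.27), chondrocyte (-0.21), osteocyte (-0.28), Wnt (-0.13), fibrous matrix (-0.28) and T and NK cell genes (0.21) were called in the same direction. Interferon (-0.10) and respiratory chain genes (-0.08) were called in the other direction, and cell cycle (0.04), macrophage (0.08) and erythroid genes (0.10) were not called, while B cell (-0.23), stromal reticular (-0.22) and ribosomal genes (-0.07) were newly called lower. Several other omissions called ribosomal genes higher, such as sham_6wk replicate 4 (0.18), and osteoblast genes lower, such as DMM_6wk replicate 3 (-0.49). Leaving out DMM_1wk replicate 1 ended the call of osteocyte (-0.06), fibrous matrix (-0.13), Wnt (-0.09), endothelial (-0.01) and T and NK cell genes (0.08). Of 16 omissions, 9 ended the osteocyte call, 6 those of T and NK cell and of interferon genes, 5 those of endothelial and of respiratory chain genes, and 3 those of fibrous matrix and of erythroid genes.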

How the results depend on the processing

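The 6-against-1-week comparison averaged over both surgeries, and leaving sham_6wk replicate 2 out where its group was not compared, were chosen after seeing the data, and the other alternatives were planned. Where a value moved, the cause was not tested.

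The preset correlation decided the gene lists. With an estimated correlation camera called 0 lists in each of the 7 comparisons, and fry called 0 in 5 of them, 4 between the times after DMM and 9 for the averaged time comparison. The authors' values gave 4 lists for DMM against sham at 6 weeks and 5 for the average DMM effect. Array weights gave 4 at 6 weeks. Slide 2 alone gave 13 lists between the times after sham and 9 for the change of the DMM effect.

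For the 247 genes of the averaged time comparison, the count was 0 with median scaling, 0 with no filter on dim probes (36827 genes tested) and 0 within slide 1 or slide 2 (4 arrays against 4). It was 408 with normexp, 451 with probes above background on all 16 arrays (22359 tested), 409 with trend and robust variance, 645 with slide as a block and 5884 with array weights. Quantile normalization (199), the authors' values (330) and the mean of probes (342) stayed within 1.5 times. Slide block and array weights shared 247 of the 247 genes, trend and robust 241, the stricter filter 214 and normexp 202.

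Array weights were 0.0757 for sham_6wk replicate 2 and 9.12 for replicate 3, against 0.957 for replicate 1 and 0.930 for replicate 4. The weighted sham 6-week mean thus rested mostly on replicate 3. In the DMM 1-week group replicate 4 had the highest weight (3.53). With these weights limma called 3305 genes between the times after sham, 963 after DMM and 1 (Tex52) for DMM at 6 weeks. For the change of the DMM effect it called 2 (Tex52 and an unnamed locus on chromosome 19). Tex52 is named here after its value was seen, as are the other single genes below. At an unadjusted p under 0.05 with a 1.5-fold change, counts were 182 for DMM at 1 week, 174 at 6 weeks, 186 for the change, 97 for the average, 1319 after sham, 2027 after DMM and 2074 for the averaged time comparison.

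Leaving out 1 array at a time gave 0 to 1502 genes for the averaged time comparison. The count was 1502 without sham_6wk replicate 2, 695 without DMM_1wk replicate 3, 490 without DMM_6wk replicate 3 and 311 without sham_1wk replicate 3. It was 3 without DMM_6wk replicate 2 (Serpina1a, Serpina1c and Serpina1d) and 1 without sham_1wk replicate 1 (Mypn). It was 0 without sham_1wk replicate 2 or 4, sham_6wk replicate 1, 3 or 4, DMM_1wk replicate 1, 2 or 4, or DMM_6wk replicate 1 or 4, so this call depended on single arrays. Genes ranged from 0 to 0 for DMM at 1 week, the change and the average, from 0 to 1 at 6 weeks (Gm16299 without DMM_6wk replicate 3), from 0 to 1 after sham (Mypn without sham_1wk replicate 1) and from 0 to 27 after DMM (27 without DMM_1wk replicate 3).

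Called lists ranged from 7 (without DMM_1wk replicate 1; 9 without replicate 4) to 17 for DMM at 1 week, from 3 (without sham_6wk replicate 2) to 12 at 6 weeks, from 8 (without DMM_6wk replicate 1) to 19 for the change, and from 4 (without sham_6wk replicate 2) to 13 (without DMM_1wk replicate 2) for the average. They ranged from 17 to 22 after sham, 17 to 19 after DMM and 19 to 22 for the averaged time comparison.

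Of the 24 named genes past the threshold in the averaged time comparison, 109 of 285 alternative values and 286 of 384 leave-one-out values lost the call, and 0 changed sign. The named genes not past it changed sign in 19 of 697 alternative and 29 of 486 leave-one-out values for DMM at 1 week, and in 64 of 693 and 38 of 432 at 6 weeks.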

Other observations

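The exact permutation tests of list means, the comparison averaged over both surgeries and the tests of marrow share and of sham_6wk replicate 2 in this part were chosen after the results were seen.

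Exact 2-sided permutation of the arrays between 1 and 6 weeks within each surgery group (4900 permutations, 8 arrays against 8) gave another reading of the time lists. Proteases and inhibitors had a mean change of -0.52 (exact p = 0.000408, the smallest possible, and 0.0110 adjusted over 27 lists). Hypoxia and glycolysis genes changed by -0.23 (adjusted p = 0.0221), erythroid genes by 1.02 (0.0276), immediate early genes by -0.30 (0.0276), fibrous matrix genes by -0.73 (0.0283), B cell genes by 0.68 (0.0283), platelet genes by 0.67 (0.0283), osteoclast genes by -0.47 (0.0331) and muscle genes by 0.52 (0.0331). Osteoblast (-0.55, 0.0704), osteocyte (-0.44, 0.0704), chondrocyte (0.88, 0.0795) and neutrophil means (-0.20, 0.304) did not pass. Nr4a2 (-1.47 ± 0.27), a gene induced within minutes by stress, is itself a member of the immediate early list and adds no separate evidence.

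Marrow cell types moved apart between the times. The erythroid mean rose over the neutrophil mean by 1.22, the B cell mean by 0.88 (exact p = 0.00327) and the platelet mean by 0.87 (exact p = 0.00122), while T and NK cells (0.30, exact p = 0.111) and macrophages (0.19, exact p = 0.478) did not pass. Of the most abundant genes, Hbb-bt was higher by 0.45 and Hba-a1 by 0.18, S100a9 by 0.16 and Camp by 0.10, while S100a8 (-0.05), Ltf (-0.25), Mpo (-0.16) and Elane (-0.19) were lower.

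Differences between 6 weeks and 1 week in both surgery groups were weighed against technical causes. If a larger share of marrow in the dissected bone raised all marrow lists alike, the erythroid minus neutrophil difference would not change between the times. It did (exact permutation p = 0.000408, the smallest possible), but this pair was chosen after the list changes were seen. Whether marrow share raises all these lists alike on the arrays was not tested. The test therefore does not decide, and a larger share of marrow stays open. Without sham_6wk replicate 2 limma called 1502 genes in place of 247, and with the brightness of each array as a term 735, so neither that array alone nor brightness (difference -0.19, exact p = 0.335) accounts for the count. Age and harvest session went with time and stay open and untested.

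Changes from 1 to 6 weeks after sham and after DMM, which share no arrays, had a correlation of 0.52 across genes (67.1% of the same sign), although genes are not independent replicates. Of 100 splits by time within the surgery groups, 4 gave a correlation as high, the real one included (highest other 0.658). These splits were a random draw from the possible ones, so 4 of 100 lies too near 1 in 20 to exclude chance.

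Other splits of the arrays were counted for each comparison, the real one included. For the 247 genes of the averaged time comparison, 2 of 100 splits gave as many, which is under 1 in 20. The splits were a random draw and the comparison was added after seeing the data, so this does not exclude chance. The other of these 2 splits gave 3765 genes, which points to a structure of the samples. What that split separates was not tested. At an unadjusted p under 0.05 the real split had 4455 genes, a count reached by 5 of 100 splits (highest other 8757), so by that count chance could not be excluded. In the other 6 comparisons the real count was 0, which every split reaches (35 of 35 or 100 of 100, with a highest other of 8 for DMM at 6 weeks, 3 for the change, 1 for the average and 0 elsewhere), so that count decides nothing.

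At an unadjusted p under 0.05 in limma, 28 of 35 splits gave as many genes as DMM against sham at 1 week (273, highest other 4231) and 33 of 35 as at 6 weeks (220, highest other 5385). The figures were 96 of 100 for the change (193 and 7160), 93 of 100 for the average (265 and 6343), 8 of 35 after sham (2020 and 8632) and 2 of 35 after DMM (2741 and 3484). Chance could not be excluded for these 6. The other splits did not keep the slides balanced as the real groups do, and no splits within slides were run. The split along the 2 slides gave 4231, 4402 and 8632 genes for DMM at 1 week, at 6 weeks and for time after sham, more than the real splits, and 1500 for time after DMM. With slide as a block limma called 0 genes in these 4 comparisons.

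List counts were reached by 10 of 35 splits for DMM at 1 week (real 15, highest other 18), 25 of 35 at 6 weeks (9 and 17), 35 of 100 for the change (14 and 18) and 84 of 100 for the average (8 and 21). For time they were reached by 2 of 35 after sham (21 and 21), 8 of 35 after DMM (18 and 21) and 8 of 100 averaged (20 and 22). Chance could not be excluded for any of these 7 list counts.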
